A study of Saccharomyces cerevisiae S288C with 32 samples.

How the data were processed

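Messenger RNA was measured in 32 libraries of Saccharomyces cerevisiae S288C. Per the labels' protocols, cells in YPD started from an optical density (OD600) of 0.1, reached 0.4 at room temperature, and were treated for 45 minutes with 2 mg/mL L-azetidine-2-carboxylic acid (AZC, a proline analog that cells build into proteins in place of proline) or with sterile water. Poly(A) RNA was selected with oligo-dT beads and made into libraries with a kit that does not mark strand, per the labels' protocols. The labels give 8 groups of 4 libraries. Flowcell 1 held wild type and zuo1, each with vehicle and AZC, and flowcell 2 held wild type and not5, each with vehicle and AZC. The labels call the 4 libraries of a group biological replicates without saying whether they came from separate cultures or whether a shared number marks a shared culture, so p-values measure the spread between these libraries.

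The authors deposited 1 table of estimated counts per gene, the expected counts that Salmon 1.10.2 gives, against the R64 genome, with read quality checked by FastQC 0.12.1, per the submitters' processing notes. Of its values 79.1% were not whole, and all were rounded to whole numbers for the tests. The table held 6085 records, of which 6084 matched a gene of the RefSeq R64 annotation. The 1 unmatched record held at most 0.0179% of any library and took no part in what follows. The matched records were 5961 protein-coding genes, 10 ribosomal RNA locus records and 114 other noncoding genes. The table held 0 of the 8 listed mitochondrially encoded transcripts. The annotation's gene models hold coding sequence without UTRs, so gene length is coding length. Because strand was not marked, the 281 records that overlap another annotated gene are uncertain, as are genes with a near-identical copy, among which Salmon divides shared reads by estimation.

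Depth was 22152108 to 31485394 counts per library on flowcell 1 and 58229383 to 97010130 on flowcell 2. In a comparison with a group at 0 counts, the fold was computed against a floor of 3 counts over that group, which covers counting error only. Reads carried no molecular identifiers in the deposited table.

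Gene tests used edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors, filterByExpr by group) in R 4.3.3, on the 16 libraries of 1 flowcell at a time, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The filter left 5783 genes on flowcell 1 and 5850 on flowcell 2. Each mutant was compared only with the wild type of its own flowcell, and the difference of AZC responses was tested as an interaction in the same fit. Positive log2 fold changes are AZC over vehicle or mutant over wild type, and errors are SE for fold changes and SD for CPM (counts scaled to a common library total, with TMM factors). The fit was tested on simulated counts with 50 genes changed at each of 4 sizes. It recovered 40 to 44% of 1.25-fold and 88 to 90% of 1.5-fold changes for AZC in wild type, 30% and 92% for AZC in zuo1, 44% and 88% for AZC in not5, 38 to 48% and 88 to 90% for the mutants in vehicle, and 8 to 18% and 56 to 58% for the interactions, with 2 to 8 false calls each. Only genes with a mean of at least 10 CPM were changed, so the rates do not cover weaker genes. The simulated genes varied independently, and the simulated libraries share no structure between equal numbers. The rates so do not give the recovery in the real not5 libraries, where equal numbers varied together.

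Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 4 tested members, with adjustment over 26 lists on flowcell 1 and 27 on flowcell 2. They were Hsf1 core chaperone targets, other heat-inducible chaperones, Msn2/4 general stress genes, cytosolic ribosomal proteins, ribosome biogenesis, Gcn4 amino acid biosynthesis, proteasome subunits with RPN4, the ER unfolded protein response, Yap1 oxidative stress genes, Pdr1/Pdr3 drug resistance genes, pheromone and mating genes, a-specific genes, alpha-specific genes, auxotrophic and mating-locus markers, the Ccr4-Not complex, mRNA decapping and decay, ribosome quality control, ribosome-associated chaperones, proline synthesis and uptake, sulfur and methionine genes, glycolysis and fermentation, the TCA cycle and respiration, cell wall integrity genes, the iron regulon, the phosphate regulon, histones, cyclins and the mitochondrially encoded transcripts. Ribosomal proteins were picked by symbol, which also took in RPP1, a subunit of RNase P and RNase MRP. Counts "adjusted over the list alone" repeat the adjustment among a list's tested members. Where an estimated correlation is given, it came from the fit with group as the only term. Variation shared by libraries of equal number so enters that estimate.

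The designs, tests, lists, most alternatives and the rule for named genes were set before the data were examined. The rule named the 5 protein-coding genes with the largest rise and the 5 with the largest fall at an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 10 CPM and groups that do not overlap (for interactions, without the last condition and the fold minimum). It added 3 called members of every list that camera called and always ZUO1, NOT5, SSA4, HSP82 and GCN4. Other genes in the text were chosen after their values were seen.

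Gene properties came from the 5961 coding sequences. They were the share of proline codons, the codon adaptation index against ribosomal protein genes, and coding length. Each was correlated across genes with log2 CPM in each library (Spearman), and libraries were compared by a 2-sided exact permutation test over all 70 assignments of 8 libraries, with adjustment over 18 tests. Overlaps of called genes were set beside the number expected of independent lists, and the share that common controls add was simulated.

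Whether equal numbers pair libraries was decided before any fits were compared, from the correlation of deviations from group means over 5667 genes with a mean count of at least 50, with all 4 pairs over 0.1 required. Vehicle and AZC libraries of the same number were paired in wild type on flowcell 1 (0.22 to 0.47), in wild type on flowcell 2 (0.23 to 0.55) and in not5 (0.48 to 0.91), as were vehicle libraries of wild type and zuo1 (0.22 to 0.37). Between replicates of a group Pearson's r of log2 CPM was 0.974 to 0.997, and no 2 libraries were alike within sampling noise (chi-square per gene 22.7 to 1220).

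Alternatives tried were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no filter, a filter at 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 32 libraries or only the 8 compared in the fit, both flowcells in 1 fit, a fold minimum, and leaving out each library. Blocks per genotype and within 8 libraries, exact tests within pairs, gene lists without members at 0 counts in a vehicle group, fits without rRNA records, and fits without the rRNA-rich libraries were chosen after seeing the data. Tables and figures were made with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9).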

Results

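RNA-seq counts were analysed for 32 poly(A) libraries of S. cerevisiae S288C, in 8 groups of 4. Wild type, the zuo1 mutant and the not5 mutant were treated for 45 minutes with AZC, a proline analog, or with water. ZUO1 encodes a J-domain co-chaperone bound to ribosomes, and NOT5 a subunit of the Ccr4-Not complex, which shortens poly(A) tails and binds ribosomes. The series title asks what misfolding of nascent chains does to translation and to mRNA decay on ribosomes. These libraries measure levels of mRNA selected by poly(A), not translation, decay rates or poly(A) tail length. Effects of tail length on selection, as in not5, cannot be told apart from changes in level. Totals were 22152108 to 31485394 counts per library on flowcell 1 (wild type and zuo1) and 58229383 to 97010130 on flowcell 2 (wild type and not5).

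The mutated genes were read in every library. ZUO1 (YGR285C, chromosome VII, 1061852 to 1063153, R64) had 25775 to 33003 counts in the 4 wild-type vehicle libraries of flowcell 1 and 0 in the 4 zuo1 vehicle libraries, at least 38300-fold lower. In the AZC libraries it had 14757 to 20188 counts in wild type, 0 in 3 zuo1 libraries and 3 in zuo1 AZC replicate 1. NOT5 (YPR072W, chromosome XVI, 690107 to 691789) had 10967 to 12928 counts in wild-type vehicle and 12188 to 17767 in wild-type AZC libraries of flowcell 2, and 0 in all 8 not5 libraries, at least 19500-fold and 16100-fold lower. LEU2, a leucine synthesis gene often used as a selection marker, had 0 counts in every wild-type and zuo1 library and 1448 to 2311 counts in not5 vehicle libraries, at least 2150-fold higher than wild type. In not5 AZC libraries LEU2 had 1378 to 2051 counts, at least 2720-fold higher. LEU2 counts went with not5 in every library. Differences between not5 and wild type so cannot be told apart from effects of LEU2. Ribosomal RNA records held 1.47% ± 0.814 (SD, n = 4) of counts in wild-type vehicle and 1.08% ± 0.36 in zuo1 vehicle libraries of flowcell 1. On flowcell 2 they held 1.56% ± 1.60 in wild-type vehicle and 6.997% ± 5.29 in not5 vehicle libraries.

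AZC in wild type raised chaperone genes by up to 282-fold and lowered the genes that build ribosomes. On flowcell 1 the cytosolic Hsp70 gene SSA4 (YER103W, chromosome V, 364589 to 366517) went from 61.3 ± 15.7 to 17289 ± 2474 CPM (SD, n = 4 per group), a log2 fold change of 8.14 ± 0.24 (edgeR adjusted p = 8.94e-15). The small heat shock protein gene HSP42 (YDR171W, chromosome IV, 806621 to 807748) rose by 7.88 ± 0.18, BTN2 (YGR142W, chromosome VII, 772454 to 773686), whose product sequesters misfolded proteins, by 6.72 ± 0.16, and the disaggregase gene HSP104 by 6.41 ± 0.16. HSP82 (YPL240C, chromosome XVI, 96496 to 98625), an Hsp90 gene with a near-identical copy, HSC82, went from 269 ± 29.6 to 9233 ± 692 CPM (log2 5.10 ± 0.14). The largest falls were in RFU1 (YLR073C, chromosome XII, 281019 to 281621), an inhibitor of a deubiquitinase (−3.41 ± 0.19), GFD2 (−3.28 ± 0.15), NOG2, a GTPase of 60S subunit assembly that overlaps a snoRNA gene (−3.18 ± 0.16), and the rRNA processing genes DHR2 (−2.72 ± 0.10) and UTP23 (−2.66 ± 0.12). Of 5783 genes tested by edgeR, 3738 changed, 1925 higher and 1813 lower, and 924 of them by at least 2-fold (501 higher, 423 lower).

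Protein folding and protein turnover lists rose with AZC on flowcell 1. All 18 Hsf1 core targets were higher (median log2 3.48; camera adjusted p = 1.72e-47, and adjusted p = 0.000443 with an estimated correlation), as were all 15 other heat-inducible chaperones (median 2.13, with SSE2 at 4.50 ± 0.14; 1.56e-17, and adjusted p = 0.00027 with an estimated correlation). All 33 proteasome genes rose, led by their activator RPN4 (2.05 ± 0.11) and RPN9 (1.12 ± 0.12), with a list median of 0.76 (camera adjusted p = 3.22e-10, and adjusted p = 0.0466 with an estimated correlation). Of 15 genes of the ER unfolded protein response 9 rose, among them ERO1, which makes disulfides (3.13 ± 0.08), and the ER Hsp70 gene KAR2 (2.25 ± 0.09), while FPR2, named after its value was seen, fell by 0.35 (camera adjusted p = 0.0017, and adjusted p = 0.0243 with an estimated correlation). Msn2/4 general stress genes were higher in 28 of 30 members (median 2.15), including TSL1 of trehalose synthesis (4.58 ± 0.25) and the polyubiquitin gene UBI4 (4.04 ± 0.12). That list had a camera adjusted p of 4.69e-12, and adjusted p = 0.28 with an estimated correlation. Cell wall integrity genes rose in 12 of 16 members, such as PRM5 (3.15 ± 0.12) and SRL3 (2.59 ± 0.12), and CRH1 fell by 0.42 (camera adjusted p = 0.00278, and adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone, these 6 lists gave the same counts as over all genes.

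Growth lists fell on flowcell 1. All 39 ribosome biogenesis genes were lower (median −1.65; camera adjusted p = 3.68e-36, and adjusted p = 0.0256 with an estimated correlation), for instance RRS1 (−2.41 ± 0.11), NSR1 (−2.23 ± 0.14; 356 ± 93.0 against 1678 ± 75.5 CPM) and the helicase gene DBP3 (−2.23 ± 0.10). Of 136 cytosolic ribosomal protein genes 129 fell and 0 rose, 130 adjusted over the list alone, with a median of −0.70 (camera adjusted p = 8.71e-08, and adjusted p = 0.696 with an estimated correlation). RPL22B (−2.03 ± 0.21) and RPL4B (−1.38 ± 0.16), each with a close paralog, were among them, and RPP1, an RNase P and RNase MRP subunit picked up by its symbol, fell by 1.64. Phosphate regulon genes fell in 13 of 16 members, 14 adjusted over the list alone (median −0.83; camera adjusted p = 0.00846, and adjusted p = 0.678 with an estimated correlation). Among them the phosphate transporter genes PHO84, which overlaps a noncoding gene, and PHO89 changed by −2.18 ± 0.14 and −2.14 ± 0.19, from vehicle levels that were higher than in wild type of flowcell 2 (PHO84, 1350 ± 273 against 53.7 ± 39.8 CPM). GIT1 (0.52) and PHM8 (2.10) of the same list rose. All 10 histone genes were lower (median −0.59). Camera did not call the histones (adjusted p = 0.097), but did with the replicate number as a block (adjusted p = 0.0343), against adjusted p = 0.678 with an estimated correlation.

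The other 16 lists were not called by camera on flowcell 1 (adjusted p 0.112 to 0.864). Gcn4 amino acid biosynthesis had 10 of 30 members higher and 14 lower (11 and 15 adjusted over the list alone), and the transcript of the activator GCN4 itself fell (−0.83 ± 0.08). Ribosome-associated chaperones had 7 of 8 lower and 0 higher, among them the Hsp70 pair SSB1 (−0.94) and SSB2 (−0.83). Cyclins had 9 of 12 lower, with CLN2 at −1.09, and 1 higher, PCL1 (0.26). Genes of mRNA decapping and decay had 9 of 20 higher, led by EDC2 (4.18), and 8 lower. Ccr4-Not genes had 4 of 9 higher (CDC39, MOT2, CAF40 and POP2) and NOT3 lower (−0.50), and ribosome quality control genes had 5 of 13 higher, such as CDC48 (0.73), and 4 lower. Among 10 proline genes the use genes PUT1 (2.11), PUT2 (1.36) and PUT3 (0.77) and the permease gene GAP1 (0.60) rose, while the synthesis gene PRO1 (−0.96), AGP1 (−0.48) and GNP1 (−0.64) fell. The members called higher and lower were 6 and 7 of 21 sulfur genes, 8 and 6 of 37 TCA cycle genes, 2 and 7 of 15 glycolysis genes (PGK1 and ENO1 higher), 3 and 5 of 19 iron genes, 7 and 1 of 12 Pdr1/Pdr3 genes, 9 and 1 of 16 pheromone genes, 2 and 3 of 16 Yap1 genes (GRX2 and AHP1 higher), 1 and 1 of 4 marker genes, and 0 and 0 of 5 a-specific genes.

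On flowcell 2 the wild-type response to AZC ran the same way. SSA4 went from 56.9 ± 10.5 to 12140 ± 2460 CPM (7.74 ± 0.35, edgeR adjusted p = 1.30e-10), HSP42 rose by 6.62 ± 0.34, BTN2 by 6.16 ± 0.31, HSP82 by 4.53 ± 0.31 and ROQ1, a regulator of the ubiquitin ligase Ubr1, by 5.66 ± 0.38. RFU1 (−2.66 ± 0.23), GFD2 (−2.58 ± 0.20) and HPT1 of purine salvage (−2.12 ± 0.11) were among the 5 largest falls, with NOG2 and FYV5, which both overlap another gene. Of 5850 genes tested, 3824 changed, 1764 higher and 2060 lower, and 607 by at least 2-fold (309 higher, 298 lower). All 18 Hsf1 core targets (median 3.06), 13 of 15 other chaperones (1.95), 26 of 30 Msn2/4 genes (1.82), all 33 proteasome genes (0.65), 8 of 15 unfolded protein response genes (0.30) and 9 of 16 cell wall genes (0.45) rose. All 39 ribosome biogenesis genes (−1.33) and 135 of 136 ribosomal protein genes (−0.59) fell, and these counts were the same adjusted over the list alone. Camera called these 8 lists (adjusted p 8.72e-37 to 0.0295), and none of them with an estimated correlation (adjusted p = 0.103 to 0.81). That correlation was 0.857 for the Hsf1 core and 0.925 for ribosome biogenesis, against 0.312 and 0.449 on flowcell 1. It came from all libraries of the flowcell without a block, so variation shared by equal numbers enters it, and it was not estimated with a block. Histones fell in 9 of 10 members (median −0.65; camera adjusted p = 0.0654, 0.011 with the replicate block, and adjusted p = 0.81 with an estimated correlation). The phosphate regulon was not called on flowcell 2 (3 higher and 5 lower of 16, camera adjusted p = 0.944). Of 4 alpha-specific genes only MF(ALPHA)1 fell, by 2.49. Its counts in wild type were too low to pass the filter when only the 8 wild-type libraries of flowcell 2 were fitted.

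Between the wild types of both flowcells, which shared no libraries, 3214 genes were called in both, 1576 higher (585 expected of independent lists) and 1635 lower (645 expected), and 3 had opposite signs. Across 5774 genes the log2 fold changes had a Pearson r of 0.945, where genes are not independent replicates, and a slope of flowcell 2 on flowcell 1 of 0.755. A test of the difference, in a fit of only the wild-type libraries of both flowcells, found 81 of 5809 genes (34 with the larger value on flowcell 1, 47 on flowcell 2). HSP42 (1.24 ± 0.17), HSP78 (1.07 ± 0.19) and HSP104 (1.00 ± 0.17) had the larger value on flowcell 1, and PHO89 differed by −2.27 ± 0.25 (edgeR adjusted p = 0.000171).

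**Figure D1:**
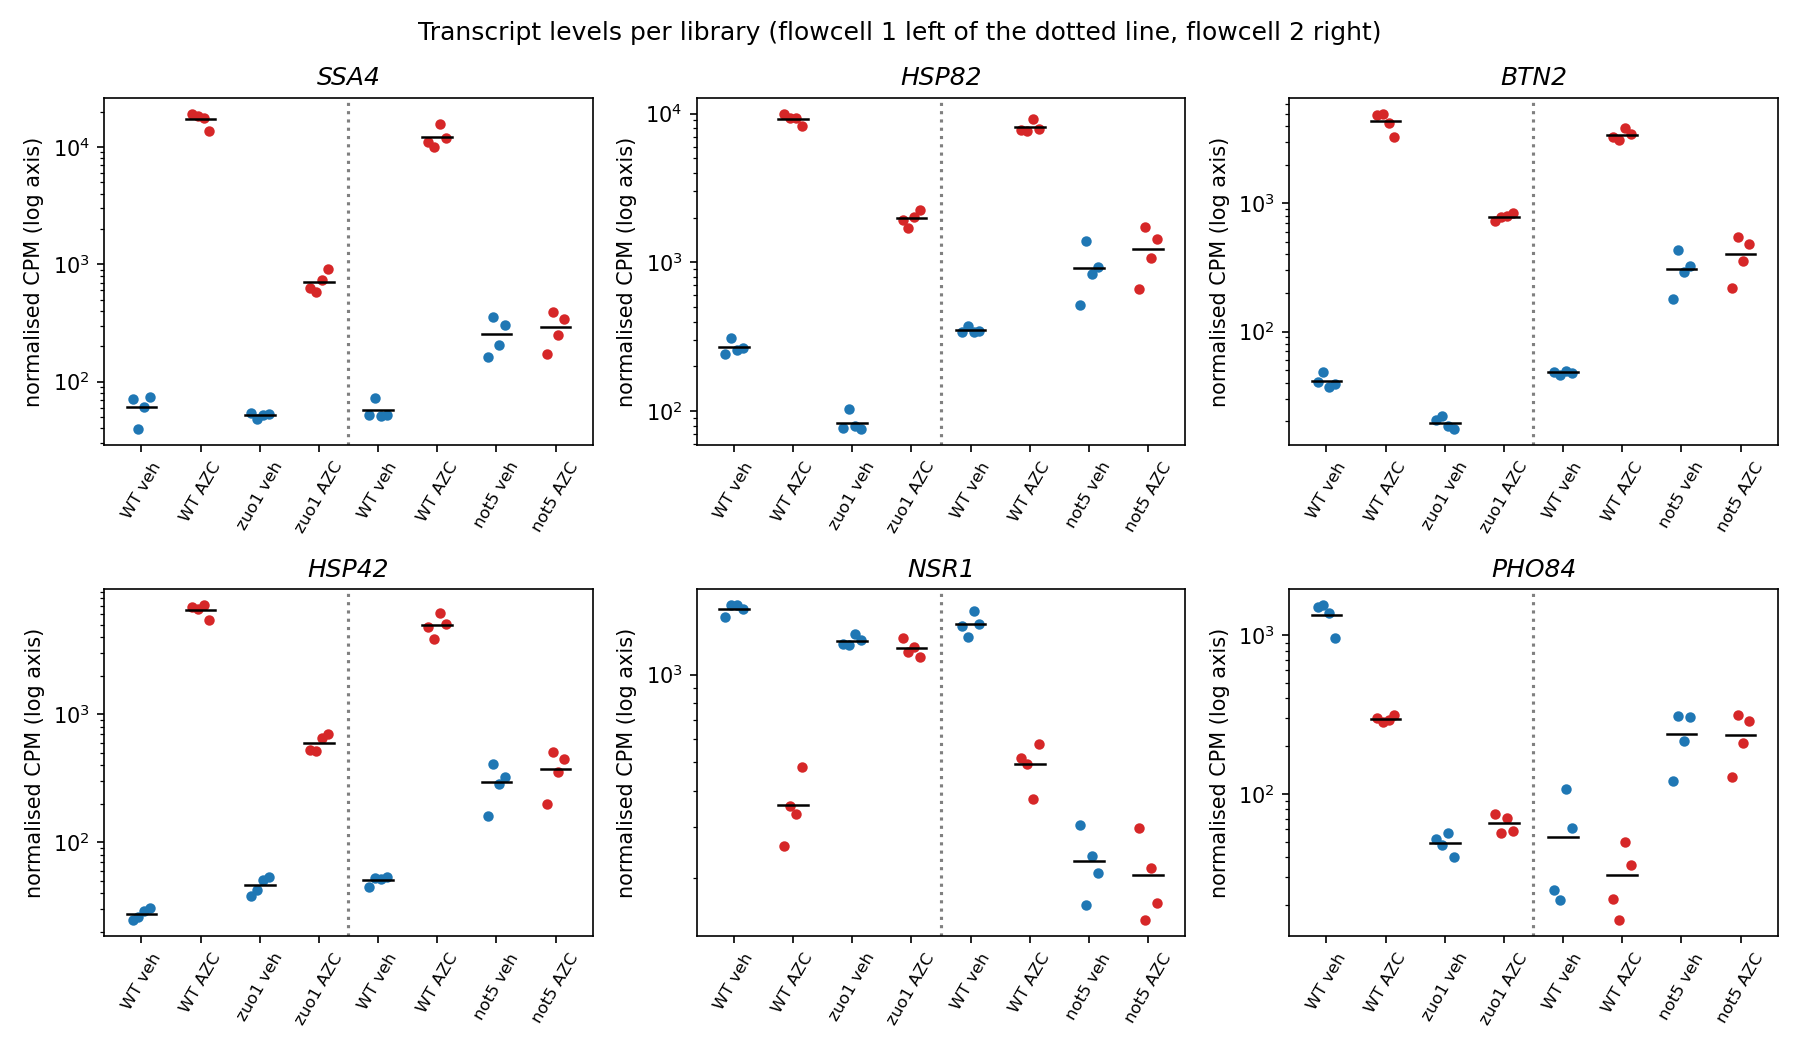
TMM-normalised CPM (log axis) of SSA4, HSP82, BTN2, HSP42, NSR1 and PHO84 in each of the 32 libraries, with bars at group means of 4 libraries and a dotted line between flowcells. SSA4 lay near 17289 CPM in wild-type AZC libraries of flowcell 1 and near 713 in zuo1 AZC libraries, while not5 libraries had means of 256 with vehicle and 290 with AZC.

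In zuo1, AZC raised chaperone genes as its largest changes, and 160 genes passed the test. BTN2 went from 19.5 ± 2.07 to 790 ± 49.1 CPM (5.34 ± 0.15, edgeR adjusted p = 6.66e-14, n = 4 per group), HSP82 from 83.8 ± 12.9 to 1976 ± 230 (4.56 ± 0.14), SSA4 from 51.9 ± 2.67 to 713 ± 147 (3.78 ± 0.20) and HSP42 from 46.1 ± 7.17 to 599 ± 97.5 (3.70 ± 0.15). SSA1, an Hsp70 gene with a near-identical copy, SSA2, rose by 3.67 ± 0.14. Of 5783 genes 160 changed, 130 higher and 30 lower, and the 48 that changed by at least 2-fold were all higher. With the replicate number as a block more genes were called, as given in the part on processing. With library totals in place of TMM, 98 rose and 42 fell, against 130 and 30.

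All 18 Hsf1 core targets rose in zuo1 (median 2.45; camera adjusted p of 4.26e-09 with an estimated correlation), and 9 of 15 other chaperones did (median 1.21; 9.11e-07), among them SSE2 (1.84 ± 0.13) and APJ1 (1.79 ± 0.09). Adjusted over the list alone the latter had 11 higher and 1 lower. KAR2 (1.72 ± 0.09) and ERO1 (1.35 ± 0.07) rose out of 15 unfolded protein response genes, 3 adjusted over the list alone (camera adjusted p = 3e-05, and adjusted p = 0.0032 with an estimated correlation). The proteasome list rose by camera (adjusted p = 9.1e-06, and adjusted p = 0.27 with an estimated correlation) with RPN4 (1.05 ± 0.11) and RPN3 (0.28 ± 0.07) called, 11 of 33 adjusted over the list alone. Msn2/4 genes (camera adjusted p = 0.00123, and adjusted p = 0.78 with an estimated correlation) had 3 of 30 higher, GRE3 (0.69 ± 0.14), PNC1 (0.64 ± 0.12) and UBI4 (0.52 ± 0.10), and 8 higher and 1 lower adjusted over the list alone. A term per genotype and number, chosen after seeing the data, called 11 of the 30 higher and 1 lower. Yap1 oxidative stress genes fell in 6 of 16 members (12 lower and 1 higher adjusted over the list alone), such as the thioredoxin gene TRX2 (−0.82 ± 0.20) and TRR1 (−0.74 ± 0.17), with a median of −0.48 (camera adjusted p = 4.45e-05, and adjusted p = 0.423 with an estimated correlation). Ribosome biogenesis had 0 members called (median −0.03; camera adjusted p = 0.323). Ribosomal proteins (median −0.14) and histones (median −0.20) also had 0, while camera gave adjusted p = 0.00194 and 0.032, and adjusted p = 0.869 and 0.718 with an estimated correlation.

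Among the remaining lists single members passed in zuo1, named after their values were seen. They were PUT1 (1.06) and PUT2 (0.46) of proline use, EDC2 (1.60) of decapping, CTH1 (0.97), which speeds decay of iron-related mRNAs, PRM5 (0.80), PGK1 (0.50) and HOM3 (0.48) higher, and CYC1 (−0.56) and CLN2 (−0.32) lower. GCN4 differed by −0.02 ± 0.08 (adjusted p = 0.953). RPN3 (adjusted p = 0.0453), TRX2, TRR1 and TSA1 (0.0458) lost their calls when any of 5 to 7 of the 8 single libraries was left out, and the count of called genes was 107 to 216 over those fits.

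The responses of zuo1 and wild type differed, by interaction, at 2898 of 5783 genes (1356 with the higher and 1542 with the lower value in zuo1; 803 by at least 2-fold). SSA4 rose less in zuo1 by −4.36 ± 0.26 (edgeR adjusted p = 5.62e-10), HSP42 by −4.18 ± 0.20, TSL1 by −3.89 ± 0.32 and HSP104 by −2.83 ± 0.18. HSP82 differed by −0.54 ± 0.17 (adjusted p = 0.0132), a call lost without zuo1 vehicle replicate 2 (adjusted p = 0.0676), without zuo1 AZC replicate 2 (0.0532) and with all 32 libraries in the fit (0.117). Lower values in zuo1 were called for 16 of 18 Hsf1 core targets (median −0.73; adjusted p = 0.129 with an estimated correlation), 14 of 15 other chaperones (−1.03; 0.00346), 25 of 30 Msn2/4 genes (−1.88; 0.252), 32 of 33 proteasome genes (−0.66; 0.128), 6 of 15 unfolded protein response genes (−0.21; 0.128) and 9 of 16 cell wall genes (−0.43; 0.464). Higher values in zuo1, where wild type fell, were called for all 39 ribosome biogenesis genes (1.60; adjusted p = 0.0298 with an estimated correlation), 74 of 136 ribosomal protein genes (0.57; 0.791) and 12 of 16 phosphate genes (0.98; 0.563), with 2 lower, PHM8 and GIT1. In the phosphate list wild type fell from a high vehicle level, PHO84 being at 1350 ± 273 CPM in that group, 49.4 ± 7.17 in zuo1 vehicle and 53.7 ± 39.8 in wild-type vehicle libraries of flowcell 2. Adjusted over the list alone the chaperone list had 15, the Msn2/4 list 27 and the ribosomal protein list 77, and camera with the preset correlation called all 9 lists (adjusted p 2.45e-43 to 0.0292). The median over all genes was −0.05, and −0.12 with library totals.

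In not5, no gene passed the edgeR test for AZC with group as the only term. Of 5850 genes 0 were called, with 62 at an unadjusted p under 0.05, where limma-voom called 0 and DESeq2 called 1, PUT2 (0.20, adjusted p = 0.000157). SSA4 was at 256 ± 88.2 CPM with vehicle and 290 ± 98.0 with AZC (0.18 ± 0.26, 95% interval −0.376 to 0.734, edgeR adjusted p = 0.999), and HSP82 at 920 ± 361 and 1226 ± 464 (0.41 ± 0.27, −0.151 to 0.981). The intervals for BTN2 (−0.147 to 0.911) and HSP42 (−0.22 to 0.922) also lay below their wild-type responses. The not5 libraries were the richest in rRNA, at 6.997% ± 5.29 with vehicle and 6.28% ± 4.58 with AZC.

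The replicate numbers paired the not5 libraries, and a term per genotype and number, chosen after seeing the data, left small changes. It called 76 genes, 75 higher and 1 lower (TRM3, −0.17), and a paired fit of the 8 not5 libraries alone called 600 (317 higher, 283 lower), while the planned block, with 1 term per number shared by both genotypes, called 0. With that term 8 of 18 Hsf1 core targets were called higher and all 18 lay above 0 (median log2 0.28, 9.07% of the 3.05 of wild type in the same fit), among them HSP82 (0.41 ± 0.07, adjusted p = 0.0203). Also higher were the catalase gene CTT1 (0.76 ± 0.07), SIP18 (0.97 ± 0.20), RTN2 (0.66 ± 0.08) and the proline permease gene PUT4 (0.58 ± 0.07), named after their values were seen. In that fit 6 of 30 Msn2/4 genes and 1 of 15 other chaperones passed, and 0 of 39 ribosome biogenesis, 136 ribosomal protein and 33 proteasome genes did. In the paired fit 17 of 18 Hsf1 core (median 0.28, against 3.09 in the same fit of wild type) and 24 of 30 Msn2/4 genes were called higher, and 32 of 39 ribosome biogenesis genes lower (median −0.16, against −1.30). Without a block 0 members were called in any of the 27 lists, and adjusted over the list alone 1 proline gene was. Camera called 11 lists at the preset correlation, led by the Hsf1 core (median 0.28, camera adjusted p = 2.22e-15), and none with an estimated correlation (adjusted p = 0.675 for that list). Among them proline synthesis and uptake had adjusted p = 0.0454, and 0.0608 with the replicate block.

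Between not5 and wild type the AZC responses differed at 2881 of 5850 genes (1554 with the higher and 1327 with the lower value in not5; 521 by at least 2-fold), in libraries where rRNA records held 6.28% of not5 AZC and 1.38% of wild-type AZC counts. SSA4 had the largest difference (−7.56 ± 0.41, edgeR adjusted p = 6.20e-09), followed by HSP42 (−6.26 ± 0.41), BTN2 (−5.77 ± 0.38), ROQ1 (−5.35 ± 0.47) and HSP78 (−5.22 ± 0.28), and HSP82 differed by −4.12 ± 0.39. Lower values in not5 were called for all 18 Hsf1 core targets (median −2.81; adjusted p = 0.0616 with an estimated correlation), 12 of 15 other chaperones (−1.80; 0.19), 19 of 30 Msn2/4 genes (−1.61; 0.747), all 33 proteasome genes (−0.62; 0.346), 8 of 15 unfolded protein response genes (−0.25; 0.346) and 6 of 16 cell wall genes (−0.43; 0.922). Higher values were called for all 39 ribosome biogenesis genes (1.18; adjusted p = 0.747 with an estimated correlation) and 98 of 136 ribosomal protein genes (0.52; 0.922), 111 adjusted over the list alone. Camera called these 8 lists at the preset correlation (adjusted p 5.97e-42 to 0.0179), and histones, with 6 of 10 higher, only with the replicate block (adjusted p = 0.0582, 0.00921 with the block, and adjusted p = 0.922 with an estimated correlation). GCN4 differed by 0.56 ± 0.08.

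**Figure D2:**
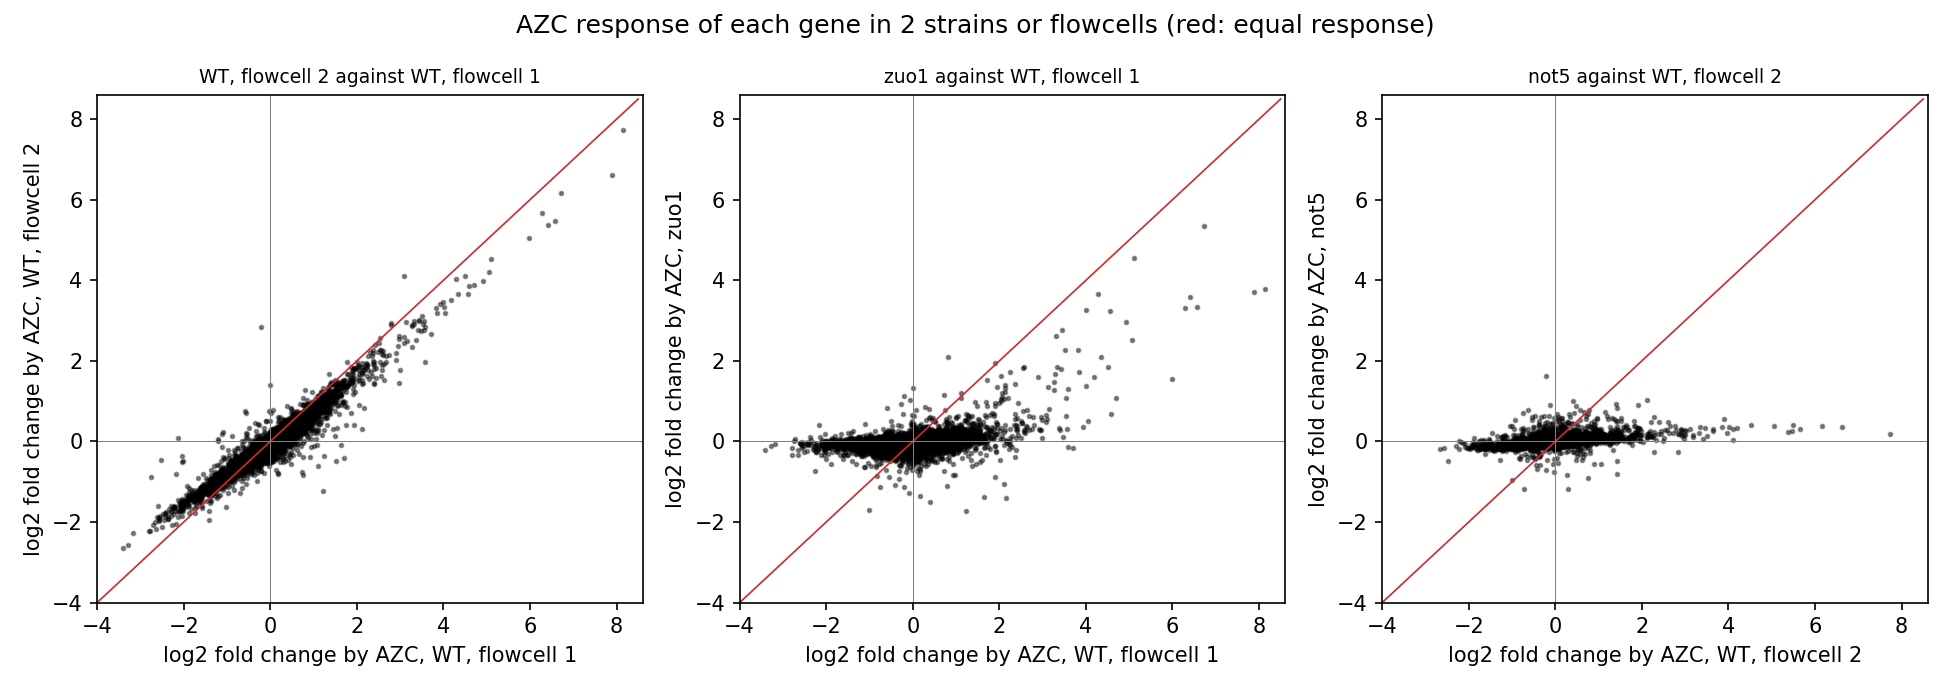
AZC log2 fold changes of single genes as points, for wild type of flowcell 2 against flowcell 1, zuo1 against wild type of flowcell 1 and not5 against wild type of flowcell 2, with a red line where both responses are equal. The Pearson r across genes was 0.945, 0.497 and 0.315, and the slopes were 0.755, 0.165 and 0.0771.

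In vehicle, the largest falls of zuo1 against the wild type of its flowcell were in the phosphate regulon, where that wild type also stood apart from the other one. The phosphate transporter gene PHO84 (YML123C, chromosome XIII, 24037 to 25800, overlapping a noncoding gene) was at 49.4 ± 7.17 CPM against 1350 ± 273 (−4.77 ± 0.16, edgeR adjusted p = 7.47e-13), and the acid phosphatase genes PHO12 (−4.77 ± 0.16) and PHO11 (−4.19 ± 0.18), near-identical copies, were also lower. In wild-type vehicle libraries of flowcell 2, not tested against either group, PHO84 was at 53.7 ± 39.8 CPM, PHO12 at 37.8 ± 22.9 and SPL2 at 2.20 ± 1.13, closer to zuo1 than to wild type of flowcell 1. SPL2, a regulator of phosphate uptake, was lower at 1.22 ± 0.238 against 31.7 ± 7.02 CPM. HSP12, a membrane stress protein gene, was higher (3.35 ± 0.61), as were the thioredoxin gene TRX2 (2.29 ± 0.20) and the glycine cleavage genes GCV1 (2.23 ± 0.22) and GCV3 (2.21 ± 0.15). HSP12 rose by 4.27 without wild-type vehicle replicate 4. Of 5783 genes 3428 differed, 1742 higher and 1686 lower (50.8% higher), and 512 by at least 2-fold (368 higher, 144 lower). With library totals 2893 were higher and 789 lower (78.6% higher), and the median over all genes moved from 0.01 to 0.25, so directions are relative to that median.

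By list, 14 of 16 phosphate genes were lower in zuo1 than in wild type of flowcell 1 (median −2.16; camera adjusted p = 9.75e-25, and adjusted p = 0.0216 with an estimated correlation), a comparison that rests on the high levels of that wild type (PHO84, 1350 CPM against 53.7 on flowcell 2). Of the 7 ribosome-associated chaperones other than ZUO1, which is at 0 counts in zuo1 vehicle libraries, 4 were lower, among them SSB2 (−0.87 ± 0.12) and its near-identical copy SSB1, and 0 higher (median −0.42). Camera did not call these 7 (adjusted p = 0.216, and adjusted p = 0.487 with an estimated correlation), and its call of the list with ZUO1 (adjusted p = 1.66e-07 and 0.00894) rests on that gene. Hsf1 core targets were lower in 13 of 18 members, such as HSP82 (−1.68 ± 0.12), SSA1 (−1.53 ± 0.13) and SSA2 (−1.54 ± 0.12), and higher in HSP42 (0.74) and HCH1 (0.32), with 14 lower and 3 higher adjusted over the list alone (camera adjusted p = 4.48e-06, and adjusted p = 0.45 with an estimated correlation). Gcn4 targets were lower in 20 of 30 members, for example BAT1 (−1.64 ± 0.10) and HIS4 (−1.42 ± 0.14), and higher in HIS5 and ARG3, and GCN4 was lower (−0.52 ± 0.08). Glycolysis genes were lower in 12 of 15, such as PGI1 (−1.24 ± 0.12) and ADH1 (−1.23 ± 0.17). Camera called both lists (adjusted p = 3.85e-06 and 6.92e-05), with adjusted p = 0.45 and adjusted p = 0.488 with an estimated correlation. Yap1 genes were higher in 10 of 16, such as GTT2 (1.85 ± 0.15), and Msn2/4 genes in 17 of 30 with 3 lower (camera adjusted p = 0.00148 and 0.00412; adjusted p = 0.488 and adjusted p = 0.819 with an estimated correlation). SSA4 did not pass (−0.24 ± 0.18, adjusted p = 0.256), but was called without wild-type vehicle replicate 2 (−0.40, adjusted p = 0.0364).

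The lists not named so far were not called for zuo1 in vehicle (camera adjusted p 0.0552 to 0.929). Ccr4-Not genes had 7 of 9 lower (median −0.48), with CDC36 and CAF130 higher, and cyclins 8 of 12 lower. NOT5 was lower (−0.35 ± 0.06), a call lost with library totals (−0.10, adjusted p = 0.258). Ribosomal proteins had 45 higher and 33 lower, ribosome biogenesis genes 5 and 20 of 39, proteasome genes 8 and 12 of 33, and decay genes 4 and 10 of 20, and the medians of these 4 lists turned from below to above 0 with library totals.

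In vehicle, not5 differed from wild type at most genes tested. The cell wall gene PIR3 (YKL163W, chromosome XI, 144401 to 145378) was at 563 ± 206 CPM against 9.18 ± 2.297 (5.94 ± 0.34, edgeR adjusted p = 2.59e-10), and the carbonic anhydrase gene NCE103 at 1729 ± 904 against 39.0 ± 3.67 (5.47 ± 0.36). Higher from low levels in wild type were SPG4 (109 ± 84.5 against 0.868 ± 0.319 CPM), TMA10 (30.8 ± 9.22 against 0.391 ± 0.183) and ECM13 (51.2 ± 21.2 against 0.932 ± 0.399). TIR1 (YER011W, chromosome V, 175248 to 176012), a cell wall mannoprotein gene, was lower (2.91 ± 0.656 against 256 ± 108 CPM, −6.45 ± 0.39), as were the mitochondrial ADP/ATP carrier gene AAC3 (−4.63 ± 0.18), the adenine deaminase gene AAH1 (−3.84 ± 0.18) and GAS3 (−3.04 ± 0.13). SPG4 rose by 6.96 ± 0.70, and by 6.26 without not5 vehicle replicate 2. Of 5850 genes 4805 differed, 2413 higher and 2392 lower (50.2% higher), and 1644 by at least 2-fold (837 higher, 807 lower). Records of rRNA held 6.997% of not5 and 1.56% of wild-type counts, and without those records 4786 genes differed. With library totals 3656 were higher and 1142 lower (76.2% higher), and the median over all genes moved from 0.00 to 0.53.

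Translation and growth genes were lower in not5. Of 136 ribosomal protein genes 134 were lower (median −1.55), for instance RPS28B (−3.02 ± 0.27), RPL9A (−2.61 ± 0.18) and RPS11B (−2.44 ± 0.11), each with a near-identical copy, and 37 of 39 ribosome biogenesis genes (median −1.37), such as NSR1 (−2.70 ± 0.23). Adjusted over the list alone, 1 ribosomal protein gene was higher and 38 biogenesis genes lower. Glycolysis genes were lower in 13 of 15 (ADH1, −1.98 ± 0.09), ENO1 (1.38) and TDH1 (0.84) being higher, and 10 of 10 histone genes were lower (HTB2, −1.33 ± 0.19). Ribosome-associated chaperones were lower in 7 of 8 (median −1.56), among them SSB1 (−2.42 ± 0.15), EGD1 (−1.67 ± 0.07) and ZUO1 (−1.63 ± 0.10). Camera called these 5 lists (adjusted p 3.73e-23 to 0.0444), and none with an estimated correlation (adjusted p = 0.516 to 0.747). The histone call, at 0.0444, ended (adjusted p = 0.0544) when the other lists were tested without NOT5 and LEU2. Of the 8 Ccr4-Not genes other than NOT5, which is at 0 counts in not5, 5 were lower, such as CCR4 (−1.30 ± 0.07) and MOT2 (−0.83 ± 0.07), and CDC36, CAF130 and POP2 higher (median −0.33). Camera did not call these 8 (adjusted p = 0.366, against 0.000495 with NOT5), and the median with NOT5 turned from −0.38 to 0.15 with library totals.

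Msn2/4, respiration, proteasome and cell wall genes were mostly higher in not5. Msn2/4 genes were higher in 29 of 30 (median 1.69), such as HSP12 (4.43 ± 0.52, and 5.30 without wild-type vehicle replicate 2) and SOL4 (4.41 ± 0.29), cell wall genes in 15 of 16 (1.76; NCW2, 3.63 ± 0.14), TCA cycle genes in 27 of 37 with ATP3 lower (0.63; SDH2, 1.95 ± 0.08), and proteasome genes in 29 of 33 with RPN1 lower (0.44; RPN4, 1.77 ± 0.09). Camera called these 4 lists (adjusted p 7.73e-06 to 0.00184), and none with an estimated correlation (adjusted p = 0.625 to 0.747). Hsf1 core targets were higher in 12 of 18 and lower in 4 (SSA2, HSC82, YDJ1 and MBF1), with a median of 0.93 that camera did not call (adjusted p = 0.272). Other stress lists went both ways, with 2 of 15 genes of the ER unfolded protein response higher and 12 lower (median −0.39), 5 of 16 Yap1 genes higher and 7 lower, and 8 of 15 other chaperones higher and 5 lower. Camera called none of these 3 (adjusted p 0.148 to 0.801). With library totals 2 of these lists turned. The unfolded protein response then had 5 higher and 4 lower (median 0.14), and Yap1 genes 10 higher and 5 lower (median 0.36, against −0.17). SSA4 (2.17 ± 0.27), HSP82 (1.39 ± 0.27), HSP42 (2.54) and BTN2 (2.68) were higher. Of the 4 marker genes other than LEU2, which is at 0 counts in wild type, TRP1, ADE2 (1.86 ± 0.08) and HIS3 (0.44 ± 0.07) were higher and LYS2 lower, and camera did not call them (adjusted p = 0.366, against 0.0365 with LEU2). GCN4 was lower by TMM (−0.19 ± 0.06) and higher with library totals (0.33, adjusted p = 0.00153).

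**Figure D3:**
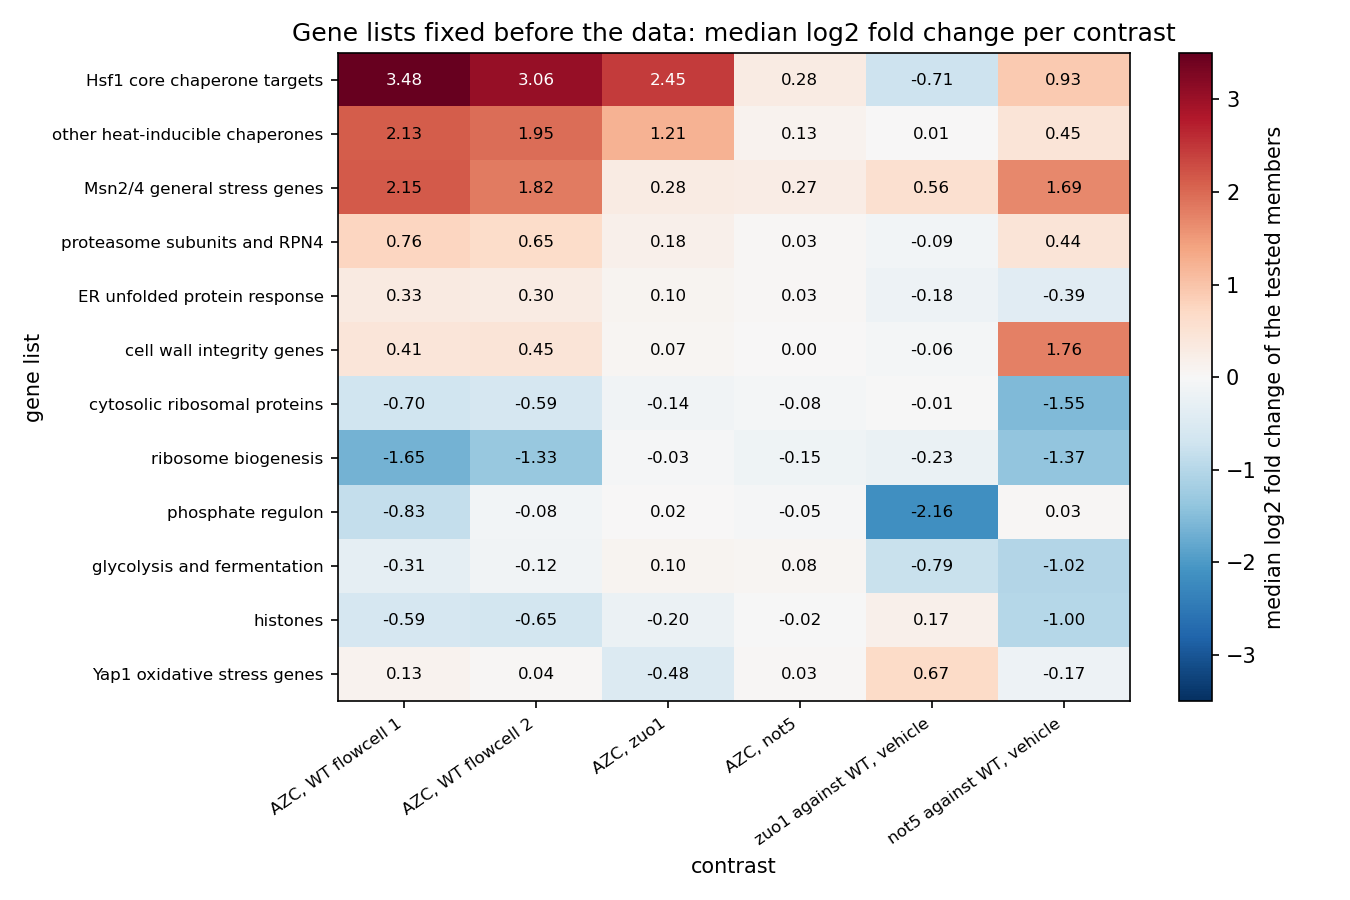
Median log2 fold change (colour) of 12 gene lists in the 6 comparisons of pairs of groups, AZC over vehicle or mutant over wild type. The Hsf1 core median was 3.48 and 3.06 for AZC in wild type, 2.45 in zuo1 and 0.28 in not5. With library totals the ribosomal protein, ribosome biogenesis, proteasome, unfolded protein response and cell wall medians turned sign for zuo1 against wild type. The unfolded protein response and Yap1 medians did so for not5 against wild type.

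Called genes were compared between AZC responses. Of the 160 genes called in zuo1, 151 were also called in wild type of flowcell 1, 128 higher in both (43.3 expected of independent lists), 20 lower in both (9.41 expected) and 3 with opposite signs. Wild type of flowcell 2, which shares no fit with zuo1, gave 127 higher (39.5 expected), 21 lower (10.7 expected) and 2 opposite. The not5 list without a block was empty. With a term per genotype and number 39 of its 76 genes were higher also in wild type of flowcell 2 (22.6 expected), TRM3 lower and 3 opposite.

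The difference of each mutant strain from wild type in vehicle was set against the wild-type AZC response of the other flowcell, which avoids shared controls. For not5 Pearson's r across genes was 0.438 (covariance 0.425), with 1208 genes higher in both (795 expected of independent lists), 1208 lower in both (749 expected) and 736 opposite. For zuo1 r was 0.0522 (covariance 0.0245), with 472 higher in both (528 expected), 713 lower in both (600 expected) and 1089 opposite. Within a flowcell, where the wild-type vehicle libraries are shared, r was 0.434 for not5 and 0.16 for zuo1, against 0.488 and 0.49 in simulated groups with no effect. With no effect the simulated r follows from the shared controls alone, so the observed r cannot be measured against it. The covariances, which can be compared, were 0.354 and 0.11 there against simulated 0.0164 and 0.015.

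Correlations of gene properties with mRNA level were compared between groups. The correlation across genes between the share of proline codons and mRNA level went from −0.0042 ± 0.0132 with vehicle to 0.0579 ± 0.0152 with AZC in wild type of flowcell 1 (SD, n = 4), and from −0.0005 to 0.0534 on flowcell 2. In zuo1 it was −0.0492 and −0.0302 (exact p = 0.2), and in not5 0.0273 and 0.0318 (exact p = 0.657). The codon adaptation index correlated with level at 0.531 in wild-type vehicle libraries of both flowcells, 0.503 and 0.511 with AZC, 0.517 in zuo1 vehicle and 0.450 ± 0.011 in not5 vehicle libraries. The index is built from ribosomal protein genes, which themselves fell with AZC in wild type and were lower in not5. Its lower correlations there are so not separate from the fall of those genes. For coding length the values were 0.383 in wild type and 0.294 in zuo1 on flowcell 1, and 0.375 and 0.334 in wild type and not5 on flowcell 2, with vehicle. AZC moved the length correlation by 0.0273 in wild type of flowcell 1, with 3 of 4 pairs of equal number higher, and by 0.0312 on flowcell 2, with 4 of 4 higher (exact p = 0.0857 in both). Within pairs the exact p was 0.25 and 0.125, and 0.125 is the smallest that 4 pairs can give. In 10 of the 18 comparisons the 2-sided exact p was 0.0286, the smallest that 70 assignments can give, and none of the 18 tests passed adjustment (lowest adjusted p = 0.0515). With 10 of 18 at that smallest p, adjustment can give no lower value, however large those shifts are. The adjusted tests so do not show that the properties stayed unchanged.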

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

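Of the tests in this part, only the comparison of spread between zuo1 and wild type was set before its result was seen, and all others were chosen after the result was seen. Chance marks a single library as far from the other 3 in about 1 in 20 groups, and 29 of 461 groups were marked here, against 23.1 expected by chance.

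AZC in not5 called 0 genes by edgeR (62 at an unadjusted p under 0.05, 0 by limma-voom and 1 by DESeq2), and its response differed from that of wild type at 2881 genes. Spread between not5 libraries of different numbers hiding a response of wild-type size is argued against by the size of the change. The term per genotype and number called 76 genes and left the Hsf1 core median at 9.07% of that of wild type. The paired fit of the 8 not5 libraries called 600, against 4100 in wild type, with Hsf1 core changes of 0.11 to 0.41, against 1.51 to 6.63. The spread did hide calls of small changes, 17 of 18 Hsf1 core genes being called in the paired fit. Hsf1 core genes already standing at the wild-type AZC level in not5 vehicle libraries is argued against by a median log2 difference of −2.67 (SD between libraries 0.293), with 0 of 18 members higher. For Msn2/4 genes the same difference was −0.0773 (SD 0.443), with 14 of 30 members higher, so a high level before treatment may account for their small change and stays open. That little or no AZC reached the cells of the not5 AZC libraries could not be tested further, since Hsf1 core genes rose slightly (8 of 18 called with the term per genotype and number), and it cannot be told apart from a biological difference of the mutant.

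AZC in zuo1 called 160 genes, and its response differed from that of wild type at 2898 genes. Larger spread between zuo1 libraries is argued against by a ratio of median within-group SD of 0.939, zuo1 over wild type. An exchange of zuo1 vehicle replicate 3 with AZC replicate 2 is argued against by their difference in mean log2 level of the Hsf1 core, 2.67 (SD of the other zuo1 libraries 0.133), and by SSA4, at 48.1 to 54.4 CPM in vehicle and 577 to 910 CPM in AZC libraries. A biological difference of the mutant, which the design names, stays open, as do differences in AZC uptake, which these libraries do not measure.

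Records of rRNA held more of the counts in not5 libraries, and single libraries stood apart. They held 14.9% in not5 vehicle replicate 4, 13.1% in not5 AZC replicate 4, 3.95% in wild-type vehicle replicate 3 and 3.32% in wild-type AZC replicate 3 of flowcell 2. The 10 most abundant genes held 20.5% and 18.85% of counts in the same 2 not5 libraries. That rRNA counts set the scaling and so the calls of not5 against wild type is argued against by the fit without rRNA records, which called 4786 genes, 4675 of them among the 4805. Lower poly(A) selection in these libraries and a biological rise of rRNA fragments were not tested.

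Other splits of the libraries were fitted in the same way, 35 for each pair of groups and 60 drawn for each interaction. For not5 against wild type, where numbers did not pair the libraries, the splits exclude chance if the libraries are independent. The labels do not show that they are. The splits so do not exclude a difference of culture, day or preparation between the groups. Of 35 splits 1 was as large, the real one (4805 genes against 0). The real split was also the only one as large for AZC in wild type on flowcell 1 (3738 against at most 1) and flowcell 2 (3824 against 4). The same held for zuo1 against wild type (3428 against 0). In these 3 comparisons numbers pair the libraries, which the 35 splits ignore. Only 8 splits part all 4 pairs, too few for a share under 0.05, so the splits do not exclude chance there. The highest other among the 8 gave 1, 0 and 0 in the same order. For AZC in wild type, chance is argued against by the 2 flowcells, which share no libraries. Of 3214 genes called on both, 3211 changed in the same direction. For the interactions the drawn splits mixed strains among AZC and among vehicle libraries. Such splits also remove the difference between strains, so they do not test the interaction alone. The real labels gave 2898 genes for zuo1, against at most 2155, and 2881 for not5, against at most 1175. For AZC in zuo1 the number of called genes alone does not exclude chance, since 2 of 35 splits gave as many, with 473 in the split that exchanged vehicle replicate 3 and AZC replicate 2 against the real 160. That tally covers the number of genes and not which genes they were. All 18 Hsf1 core targets were called higher in the real split (adjusted p = 4.26e-09 for the list with an estimated correlation), and BTN2 was at 17.4 to 21.9 CPM in vehicle and 729 to 848 CPM in AZC libraries. For AZC in not5 the tally, 35 of 35, says nothing about chance, since no split can give fewer than the real 0. The highest split gave 1858 and parted 2 of the 4 pairs. Splits that parted 0 pairs gave 1696, 2 and 0. With the correlation between libraries of equal number (0.48 to 0.91), the high counts point to a structure of the samples. The labels do not tell a shared culture from a shared day or preparation. For AZC in not5 the highest other of the 8 splits that part all 4 pairs gave 0.

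The wild-type AZC response differed between flowcells at 81 genes. In single libraries a value lay far from the other 3 of its group, relative to the range of that group, for the following genes. Where the other 3 lay close together, a small difference was enough. RPN9 in not5 vehicle replicate 3, at 322.2 CPM against 312.5 to 313.6, was such a case. In wild-type vehicle libraries of flowcell 1 UBI4 was at 102.4 CPM in replicate 4 (others 73.7 to 77.5), HSP12 at 117.3 in replicate 4 (22.01 to 28.4), GCV1 at 18.27 in replicate 4 (others at most 16.16), ERO1 at 165.7 in replicate 2 (143 to 145.6) and PGI1 at 2152 in replicate 1 (2415 to 2417). In wild-type vehicle libraries of flowcell 2 SSA4 was at 72.64 CPM in replicate 2 (51.0 to 52.3), TSL1 at 113.9 in replicate 2 (77.0 to 79.2), HSP42 at 44.58 in replicate 1 (52.0 to 53.3) and MOT2 at 113.7 in replicate 1 (100.6 to 101.7).

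Wild-type AZC replicate 3 of flowcell 2 had HPT1 at 41.38 CPM (others 63.0 to 65.4), RPL22B at 23.11 (37.3 to 40.4), RRS1 at 20.74 (30.8 to 33.0) and DBP3 at 126.6 (174 to 180.6), and a correlation of proline codon share with level of 0.0621. In zuo1, SSA1 was at 241.5 CPM in vehicle replicate 1 (335 to 343.6), SRX1 at 2.39 in vehicle replicate 2 (10.2 to 12.3), NOT5 at 156.6 in AZC replicate 2 (168.3 to 169.3) and PHO89 at 3.51 in AZC replicate 2 (4.93 to 5.01), and the correlation of codon adaptation with level was 0.5294 in AZC replicate 4. In not5, RPN9 was at 322.2 CPM in vehicle replicate 3 (312.5 to 313.6), PRM5 at 179.1 in vehicle replicate 1 (241.9 to 254.8), GCN4 at 686.8 in AZC replicate 1 (723.5 to 728) and PRE8 at 309.3 in AZC replicate 2 (277.8 to 281).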

How the results depend on the processing

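The blocks per genotype and number and within 8 libraries, the fits without rRNA records or rRNA-rich libraries, the exact tests within pairs and the lists without members at 0 counts were chosen after seeing the data, and the other alternatives before. Of the counts and values under alternatives 396 were labelled unchanged and 18 moved. Other counts and values were held to 1.5 times the reported count or to the replicate spread. Gene properties were also tested without ribosomal protein genes and in a rank regression on all properties. The gene property tests under other settings were labelled by whether they passed adjustment, whatever the size of the shift. None passed in any setting, so that label does not show that the correlations were stable. Exact tests within pairs could not be labelled otherwise, since their smallest p is 0.125. Of the values of named genes 5398 kept direction and side of the threshold, 32 lost their call, 9 gained one and 1 turned. That 1 was GCN4 in not5 against wild type with library totals (0.33, SE 0.084, adjusted p = 0.00153), where scaling moved the median of all genes.

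With a fold minimum of 2 the counts were 924 and 607 for AZC in wild type on flowcells 1 and 2, 48 for AZC in zuo1, 512 and 1644 for zuo1 and not5 against wild type, and 803 and 521 for the interactions, by construction. The overlap of both wild types was then 580 and that of wild type and zuo1 48. Calls for AZC in not5 were 1 with DESeq2, 76 with a term per genotype and number and 600 with the block in 8 libraries. Gene lists called were 12 with an estimated correlation and 113 with fry, against 71 of 212 with camera, and fry tests another hypothesis. Without ZUO1, NOT5 and LEU2, each at 0 counts in a vehicle group, 67 lists were called, all among the 71. Ribosome-associated chaperones in zuo1 and Ccr4-Not, marker and histone genes in not5, each against wild type, lost their calls, and ribosome-associated chaperones are 1 of the 12. Within 1 flowcell the zuo1 effect and the AZC response had r = 0.16, where shared controls add to r.

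Whether numbers pair the zuo1 libraries was not established (vehicle and AZC 0.08 to 0.60, against a minimum of 0.1). In zuo1 6 of 8 libraries were closest to their own number, as in wild type of flowcell 1, which passed that minimum. With the planned replicate block AZC in zuo1 called 280 genes (206 higher, 74 lower), which include all 160, with a term per genotype and number 307 and with the block in 8 libraries 275. The term per genotype and number called 11 of 30 Msn2/4 genes higher and 1 lower in zuo1, against 3 and 0, and 8 of 16 Yap1 genes lower, against 6. Numbers also did not pair wild type and zuo1 with AZC (0.02 to 0.48), wild type and not5 with vehicle (−0.17 to 0.41) or AZC (−0.30 to 0.41), or the wild types of both flowcells. The replicate block called 4040 and 4046 genes for AZC in wild type, 3730 and 4920 for zuo1 and not5 against wild type, and 3284 and 3271 for the interactions. Among lists it called 74, with histones gained in 3 comparisons, proline genes lost in not5, and iron genes gained for AZC in zuo1 (adjusted p = 0.0306, against 0.0832), and it changed no other list's call. ZUO1 in the not5 interaction was called with it (0.24, adjusted p = 0.0495, against 0.142).

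Leaving out 1 library at a time gave 3515 to 3701 and 3564 to 3763 genes for AZC in wild type, 107 to 216 in zuo1, 0 to 0 in not5, 3087 to 3437 for zuo1 and 4671 to 4789 for not5 against wild type, and 2656 to 2910 and 2547 to 3071 for the interactions. Differences in the correlation with coding length were 0.0206 to 0.0342 and 0.022 to 0.0378 for AZC in wild type, 0.0114 to 0.0431 in zuo1, −0.0097 to −0.0029 in not5, −0.0988 to −0.0845 for zuo1 and −0.0502 to −0.0344 for not5 against wild type. With codon adaptation they were −0.0322 to −0.0229, −0.0218 to −0.0164, −0.0029 to 0.0024, −0.0098 to 0.0008, −0.0161 to −0.0114 and −0.0848 to −0.076 in the same order. With proline share they were 0.0566 to 0.068, 0.0511 to 0.055, 0.0134 to 0.0265, −0.0015 to 0.0093, −0.0524 to −0.0404 and 0.0236 to 0.0325. The planned tRNA adaptation index was not run, since 34 of 275 nuclear tRNA genes in the annotation name an anticodon, and the codon adaptation index took its place. For moved counts not explained by their construction the cause was not tested. Small changes were recovered less often than large ones in simulated counts, in which depth and spread were not varied.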

Other observations

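Genes of proline use and uptake also differed between strains before treatment, and were chosen here after their values were seen. In not5 vehicle libraries the proline permease gene PUT4 (3.70 ± 0.30), the proline oxidase gene PUT1 (2.74) and the general amino acid permease gene GAP1 (2.15) were higher than in wild type, and the proline synthesis gene PRO1 (−1.01) was lower. Of 10 members 6 were higher and 4 lower, and camera did not call the list (adjusted p = 0.376). In zuo1 vehicle libraries PUT1 (1.41) and PUT4 (1.01) were higher and 4 members lower. AZC raised PUT1 (1.41) and PUT2 (1.03) also in wild type of flowcell 2.

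Among iron genes AZC in wild type of flowcell 1 raised CTH1 (1.45), ISU1 (0.35) and the ferric reductase gene FRE2 (0.33) and lowered the high-affinity uptake genes FET3 (−1.39), FTR1 (−1.47) and FRE1 (−1.62), the siderophore transporter gene SIT1 (−1.50) and VHT1 (−0.79). The other 11 of the 19 were not called, and camera did not call the list (adjusted p = 0.864). In not5 against wild type 13 of 19 iron genes were higher and 4 lower (camera adjusted p = 0.361), and the sodium-phosphate transporter gene PHO89 was higher (5.43 ± 0.39).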
